A study of Mus musculus with 3 samples.

How the data were processed

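Gene expression was measured in NIH3T3 cells, an immortalised mouse embryonic fibroblast line, on 3 single-colour oligonucleotide arrays of 45101 probe sets each. Total RNA was extracted with a phenol-based reagent and biotin-labelled, per the labels' protocols. 2 arrays held cells with the empty vector (replicates 1 and 2) and 1 array held cells with a short hairpin RNA (shRNA) against retinol saturase, numbered 2 in its title. What that number stands for is not given in the sources used here. Groups and numbers were taken from the sample titles.

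The deposited values are probe set intensities on a linear scale. Software, scanner settings and summarisation method are not given in the sources used here. In the deposited intensities the 2% trimmed mean over all probe sets was 250 on each array, so the arrays had been scaled to a common level before deposit. Signals ran from 0.1 to 30189.8. No detection calls were used here, so it is not known which dim probe sets stood above background. Precision is limited by the number of arrays.

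Gene names came from the platform annotation given for these probe sets and were looked up by gene ID in the annotation of mouse assembly GRCm38.p6, which changed 0 symbols. Of the probe sets, 34945 had exactly 1 gene symbol, 932 had several, 9160 had none listed, and 64 were array controls. Only the first kind was used. They stand for 18193 genes. A gene was represented by its probe set with the highest mean log2 signal over the 3 arrays. An offset of 10.2, the 25th percentile of all deposited values, was added before taking log2, so fold changes are on the log2(signal + offset) scale and understate the change of dim genes. No further normalization was applied, because the trimmed means agreed within 10%. Genes were tested when their mean log2 signal reached the median over all probe sets, which left 10843 genes.

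The comparison of RetSat shRNA with empty vector was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes over all 3 arrays, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 1 residual degree of freedom per gene, from the 2 empty-vector arrays, and the lone RetSat shRNA array is assumed to vary like them. Nothing in the labels says whether the empty-vector arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Because 1 array has no spread of its own, a rule of size was used beside the model, which took genes at least 2-fold from each empty-vector array in the same direction. The model and the rule were tested on simulated data with the tested genes' levels. With the spread seen between the empty-vector arrays, limma recovered 0 of 66 genes changed 8-fold, while the rule of size recovered 65 of them and also took 485 unchanged genes. With spreads from RetSat shRNA and empty vector 2, limma recovered 0 of 66 genes changed 8-fold, and the rule of size recovered all 66 and took 72 unchanged genes. In both runs each spread came from 1 gene's difference between 2 arrays, shuffled among genes of like level. Such spreads carry noise of their own, which may add to the failure of limma there. With a spread common to genes of like level, sized as between RetSat shRNA and empty vector 2, limma recovered 62 of 66 genes changed 8-fold and 50 of 67 changed 4-fold, with 1 false call, and the rule of size took 25 unchanged genes. A count of 0 from limma therefore says nothing about the size of changes at either spread drawn from single genes. The common spread was simulated only at the size between RetSat shRNA and empty vector 2 (SD of the log2 difference 0.336). The fit of the arrays takes its spread from the empty-vector arrays (SD 0.739), so that run does not bear on a count of 0 here. Every run also gave the 3 arrays equal spread for a gene, whereas here empty vector 1 stood apart from a close pair. The simulated counts of unchanged genes taken by the rule of size therefore do not carry over to these arrays.

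Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The genes named are Retsat, up to 15 genes in each direction that passed the rule of size and ranked highest by the smaller of their differences from the 2 empty-vector arrays, and up to 4 members of each list ranked the same way. Genes named outside this rule are said to be chosen after their values were seen. A list was described by the median log2 difference of its tested members and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Lists outside the central 95% are said to lie outside the range of random lists. The percentile describes these arrays and is not a p-value, and genes of a list are not independent of one another. In the simulations a list of unchanged genes came out at percentiles of 1.31 to 29.7, so a single list can fall outside by chance, and a list moved by 0.5 log2 came out at 100. Alternatives were quantile normalization, centring on the median, no filter and a stricter filter at the 75th percentile, no offset and a larger offset, other variance priors, a minimum-change test, a threshold of 0.10, a 3-fold rule, every probe set counted on its own, and leaving out either empty-vector array.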

Results

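The series set NIH3T3 fibroblasts carrying an shRNA against cells carrying the empty vector, within a screen for shRNAs that raise resistance to oxidative stress. The target here is retinol saturase (Retsat), an enzyme that saturates a double bond of retinol, and the cells with its shRNA are labelled as highly resistant to tert-butyl hydroperoxide, an organic peroxide used to impose oxidative stress. The empty-vector cells are labelled as untreated and as giving basal expression. No treatment is stated for the RetSat shRNA cells. The data are 2 empty-vector arrays and 1 RetSat shRNA array, with 10843 genes tested. The question of the comparison is which transcripts, beside the target, differed in the resistant cells.

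Retsat mRNA was strongly reduced on the RetSat shRNA array. The gene's brighter probe set read 456 ± 56.6 (SD, n = 2) with the empty vector and 69.5 with the shRNA, which leaves 15.2% of the empty-vector level. Its other probe set read 98.7 ± 11.8 (SD, n = 2) and 17.7, which leaves 17.9%. The ratio of signals was 5.98 against empty vector 1 and 7.13 against empty vector 2 for the brighter probe set, and 6.04 and 5.10 for the other. On the log2 scale the difference of the brighter probe set was -2.54 (SE 0.504), and the empty-vector arrays differed by 0.25. In limma's moderated test its adjusted p was 1 (unadjusted p = 0.000432), and it was 0.00717 when the variance prior was fitted robustly and 0.118 with the arrays centred on their medians. The target gene goes with the label of this array.

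**Figure D1:**
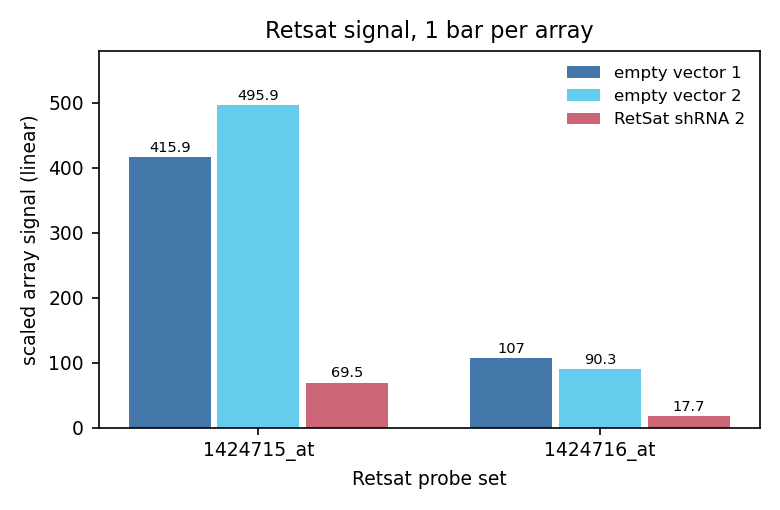
Scaled array signal (linear axis, from 0) of the 2 Retsat probe sets, with 1 bar for each array. On both probe sets the RetSat shRNA bar (69.5 and 17.7) stands below both empty-vector bars.

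The 3 arrays were unequally alike, and the one that stood apart was an empty-vector array. Across the tested genes, log2 signals of RetSat shRNA and empty vector 2 correlated at r = 0.985 (SD of the log2 difference 0.336), whereas empty vector 1 correlated at 0.924 with empty vector 2 (SD 0.739) and at 0.923 with RetSat shRNA (SD 0.754). These correlations are across genes, which are not independent replicates. A difference of at least 2-fold was seen for 188 genes between RetSat shRNA and empty vector 2, for 1381 between the empty-vector arrays, and for 1478 between RetSat shRNA and empty vector 1. The median of all tested genes lay 0.136 log2 higher on empty vector 2 and 0.141 higher on RetSat shRNA than on empty vector 1. With each array in turn set against the other 2, 1061 genes were at least 2-fold from both for empty vector 1, 66 for empty vector 2 and 64 for RetSat shRNA. Limma fits with a control array alone take their spread from the other control and RetSat shRNA as 1 group. For empty vector 1 that is the closest pair, so no counts are given from these fits. The ratio of 3' to 5' signal of the Actb control probe sets, which rises as RNA degrades, was 1.53, 1.53 and 1.65 on empty vector 1, empty vector 2 and RetSat shRNA, and that of Gapdh was 0.841, 0.931 and 0.931.

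Cell cycle genes were among those that set empty vector 1 apart. Of the 33 tested, 9 were at least 2-fold higher on it than on both other arrays and 0 at least 2-fold lower. Of all 10843 tested genes, 859 were higher and 202 lower by the same rule. The single genes named in this paragraph were chosen after their values were seen. Mki67, the Ki-67 proliferation antigen, read 3234 on empty vector 1 against 125 on empty vector 2 and 122 on RetSat shRNA. Top2a, a DNA topoisomerase, read 5904 against 655 and 624. Cenpe, a kinetochore motor, read 910 against 50.3 and 60.1, and the cohesin subunit Smc3 read 1886 against 168 and 106. The extracellular proteoglycan Vcan read 2778 against 258 and 235. The log2 differences of these genes from the mean of the other 2 arrays ran from 3.19 (Top2a) to 4.60 (Mki67). They were picked by their values on empty vector 1, so no test is given for them. Other cell cycle genes went both ways or were level. Mcm6 read 3027 against 1623 and 1309.9, Pcna read 10420 against 10141 and 10310, and Cdc20 read 4920 against 7490.3 and 7421. The transcription factor E2f1 read 259.1 against 568.2 and 493.8. Genes lower on empty vector 1 included En1, a homeobox factor, at 160.3 against 699 and 760.4, mesothelin (Msln) at 164 against 635 and 690.2, and the actin-binding Tagln at 38.4 against 166 and 198.

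No gene passed limma in the comparison of RetSat shRNA with empty vector (0 of 10843 at an adjusted p of 0.05, with 108 at an unadjusted p under 0.05). With a robust variance prior 7 genes passed, all lower, and with the arrays centred on their medians 1 gene, Kcnq1ot1, passed. Fewer than a share of 0.05 of the genes thus had an unadjusted p under 0.05 in the main fit. Its spread comes from the empty-vector arrays, which stood far apart (SD of the log2 difference 0.739), so its counts do not measure the effect of the shRNA. In the robust fit the SE was 0.546 for Retsat and 0.552 for Myo9a, so a gene's own spread hardly counted. With the arrays centred, the SE of Kcnq1ot1 was 0.64, against 1.08 in the main fit. By the rule of size, 10 genes were at least 2-fold higher and 54 at least 2-fold lower on RetSat shRNA than on both empty-vector arrays. The same rule took 66 genes with empty vector 2 as the lone array (22 higher and 44 lower) and 1061 with empty vector 1 (859 higher and 202 lower), so the count for RetSat shRNA was no larger than that for a control array. Without empty vector 1, 78 genes were higher and 110 lower, and without empty vector 2, 374 were higher and 1104 lower.

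All 10 genes on the higher side were dim, at under 200 signal units on every array. Myadml2 read 30.8 and 31.8 with the empty vector and 114 with the shRNA, and Ubxn11 read 32.5, 24.3 and 105. Pgf, a placental growth factor of the VEGF family, read 41.2, 13.4 and 107. Crocc, the rootletin of the ciliary rootlet, read 44.3, 45.4 and 112, and Rpusd3, a pseudouridine synthase, was the brightest at 81.9, 86.4 and 189. The other genes taken were Tmem190, Gm20346, 2200002J24Rik, 1700096K18Rik and Crhr1, the corticotropin-releasing hormone receptor, with RetSat shRNA signals of 79.2, 121, 76.6, 102 and 83.3.

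On the lower side, 47 of the 54 genes were under 200 on every array. Beside Retsat, those with the largest smaller difference were Pou5f2 (81.0 and 79.3 with the empty vector, 5.3 with the shRNA), a POU-domain factor, Slc22a17 (87.4, 62.0 and 3.4), a lipocalin receptor, and Prdm11 (117, 104 and 12.2). 2610316D01Rik read 63.1, 79.4 and 9.5, Gm3764 read 56.2, 79.8 and 8.7, and Zc3h6 read 77.1, 66.9 and 14.4. Hectd4, a ubiquitin ligase family member, read 175, 156 and 45.4. Dph7, which acts in diphthamide synthesis, read 53.9, 52.4 and 13, the phospholipase Pld1 read 44.5, 82.8 and 10.2, and Cep126 read 53.8, 121 and 14.1. For Crybg3, Fv1, Myo9a and the imprinted noncoding Kcnq1ot1 the empty-vector arrays were themselves far apart. Kcnq1ot1 read 872 and 64.2 with the empty vector and 16.6 with the shRNA, and Myo9a read 199.9, 39.4 and 7.3.

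Among the brighter genes Retsat stood alone. With the filter raised to the 75th percentile, 7007 genes remained, and Retsat was the 1 gene at least 2-fold from both empty-vector arrays. The same rule took 3 of these genes with empty vector 2 as the lone array and 546 with empty vector 1. Against empty vector 2 alone, 6 of these genes differed at least 2-fold, compared with 651 between the empty-vector arrays. They were chosen after their values were seen and comprised Retsat, Rps27 (871 on empty vector 2 and 292 on RetSat shRNA, but 327 on empty vector 1), Atp5md, a small ATP synthase subunit (4807 and 3715 with the empty vector, 8834 with the shRNA), Krcc1 (414, 232 and 581), 3110021A11Rik (314, 148 and 423) and Tcl1b3 (648, 273 and 1174).

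**Figure D2:**
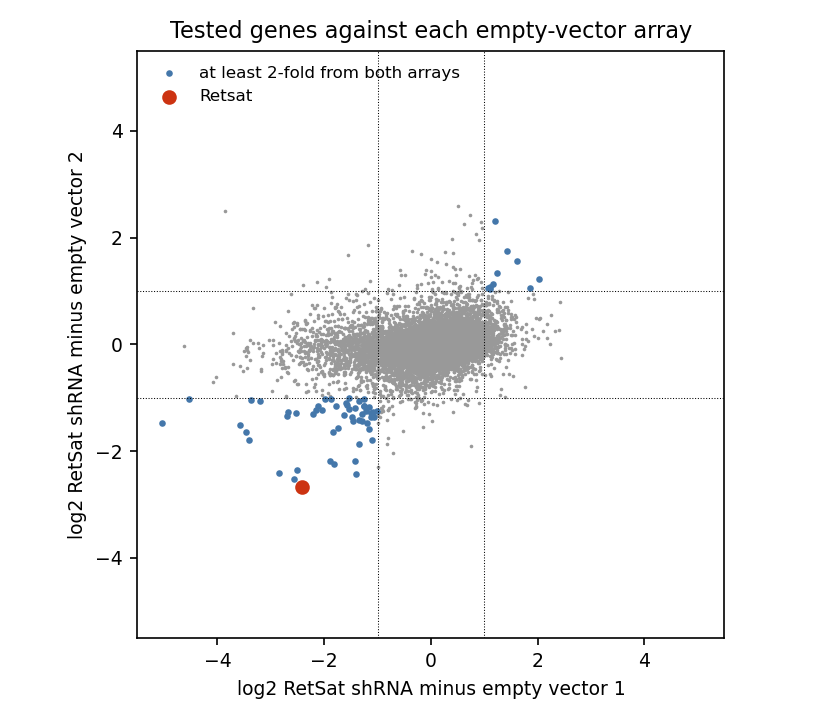
Log2 difference of RetSat shRNA from empty vector 1 (x axis) and from empty vector 2 (y axis), 1 point for each of the 10843 tested genes. The cloud is wider along x (SD 0.754) than along y (SD 0.336), and Retsat lies at -2.42 and -2.67.

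Medians of 3 gene lists lay outside the range of random lists on the same side against both empty-vector arrays. Targets of p53 were higher, with a median log2 difference of 0.67 from empty vector 1 and 0.22 from empty vector 2, and 13 of 18 tested genes exceeded both control arrays, compared with 34.4% of all tested genes. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, read 957 and 1640 with the empty vector and 2229 with the shRNA. Rrm2b, a ribonucleotide reductase subunit, read 106, 154 and 225, Trp53inp1 read 496, 618 and 835, and the antiproliferative Btg2 read 705, 823 and 1076. Cell cycle genes were lower, with medians of -0.27 and -0.12, and 16 of 33 lay below both arrays, compared with 25.4% of all tested genes. The replication licensing genes Mcm4 (2158, 1811 and 1338) and Mcm3 (1813, 1685 and 1321), Cdc6 (354, 184 and 142) and the spindle motor Kif11 (589.9, 113 and 80.5) ranked highest by the smaller of their 2 differences. Extracellular matrix genes were lower, with medians of -0.12 and -0.13, and 16 of 31 lay below both arrays. Examples were the laminins Lamb1 (2023, 1649 and 1171) and Lama4 (300.2, 174 and 129), tenascin Tnc (1840.4, 938 and 717) and periostin Postn (317, 18.8 and 4.0). Postn lay below the median signal of all probe sets on empty vector 2 (37.9) and RetSat shRNA (35.7), and its control arrays were far apart. Its difference from empty vector 2 therefore rests on signal near the floor.

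The 3 lists lay outside the range of random lists against empty vector 1 (percentiles 99.99, 0 and 0) and against empty vector 2 (99.99, 0.02 and 0). Against the mean of the empty-vector arrays, the planned comparison, 7 of the 28 lists lay outside. They were these 3 (percentiles 100, 0 and 0), retinoid genes (98.75), antioxidant enzymes (99.83), targets of ATF4 and the unfolded protein response (99.54) and hypoxia and glycolysis genes (99.28). Taken singly, 5 lists lay outside against empty vector 1, 9 against empty vector 2, and 5 in the difference between the empty-vector arrays, where 1.4 would fall outside by chance. The differences from the 2 empty-vector arrays share the RetSat shRNA array, and among random lists, whose genes are not tied as those of a pathway are, 0.1 would lie outside on the same side of both. In a comparison chosen after the result was seen, 3 lists did so with empty vector 1 as the lone array (cell cycle, growth arrest and extracellular matrix), and 0 with empty vector 2. Among random lists 0.6 and 0.0581 would do so. The lists also differed between the control arrays, where cell cycle and extracellular matrix genes lay below the range of random lists on empty vector 2 against empty vector 1 (percentiles 0.15 and 1.43) and p53 targets lay within it (96.8). Among random lists matched on gene length too, matrix genes came within the range (12.71) and cell cycle genes stayed below it (0.11). From empty vector 1 to empty vector 2 the median was 0.40 for p53 targets and -0.17 for cell cycle genes, larger than their differences between RetSat shRNA and empty vector 2, and 0.01 for extracellular matrix genes. Relative to the median of all genes, the differences of RetSat shRNA from empty vector 1 and empty vector 2 were 0.53 and 0.22 for p53 targets, -0.41 and -0.12 for cell cycle genes and -0.26 and -0.13 for extracellular matrix genes, and those between the control arrays were 0.27, -0.30 and -0.12. No member of these lists passed limma, either over all genes or adjusted over the list alone (0 genes each).

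Antioxidant enzymes lay outside the range of random lists on the higher side, and NRF2 targets and iron handling genes lay within it, all against the mean of the empty-vector arrays. NRF2 targets, which include the main inducible detoxification genes, had medians of 0.24 and -0.01 (percentiles 48.8 and 12.8), with 12 of 29 above both arrays and 7 below. The glutathione transferase Gstm3 was lower at 62.3 and 75.9 with the empty vector and 23.1 with the shRNA. Osgin1 read 62.2, 85.2 and 110.2, glutathione reductase Gsr read 706, 1087 and 1285, and transketolase Tkt read 9679, 9842 and 11746. Antioxidant enzymes had a median of 0.27 against the mean of the empty-vector arrays (percentile 99.83). It was 0.39 against empty vector 1 (percentile 97.4, within the range) and 0.10 against empty vector 2 (percentile 98.1, outside it), and 20 of 30 exceeded both arrays. Mitochondrial superoxide dismutase Sod2 read 5626, 6610 and 8578, metallothionein Mt2 read 7142, 7138 and 9142, and the methionine sulfoxide reductase Msra read 127, 121 and 175, while Msrb2 read 70.3, 73.8 and 52.9. Iron handling genes had medians of 0.14 and 0.08 (percentiles 47.1 and 88.2). Against the mean of the empty-vector arrays their median was 0.04 (percentile 38.8), and with the stricter filter, over 11 genes, it was -0.27 (percentile 0.6, outside the range). The zinc and iron transporter Slc39a14 read 487, 509.9 and 677, although another of its probe sets moved the opposite way. No gene of these lists passed limma over all genes or adjusted over the list alone.

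The retinoid list, Retsat included, had a median of 0.28 against the mean of the empty-vector arrays (percentile 98.75, outside the range of random lists) and of 0.31 and 0.01 against each (percentiles 85.6 and 63.8, within it). The list was also within the range after quantile normalization (percentile 93.3) and with the stricter filter (median 0.14, percentile 78.1). Retsat was the 1 of 15 members past the threshold when adjusted over the list alone (0 over all genes). The retinol dehydrogenases Rdh14 (558, 555 and 817) and Rdh10 (319, 310.2 and 398) were higher than both arrays and the retinoic acid binding protein Crabp1 (671, 535 and 462) was lower. Lipid and peroxisome genes had medians of 0.11 and 0.01 (percentiles 22.2 and 49.3), with the lipid droplet protein Plin2 at 2203, 1258 and 1097 and the carnitine transferase Cpt1a at 1552, 1379 and 1116. Cholesterol synthesis genes had medians of 0.25 and 0.10 (percentiles 51.6 and 98.1), with Mvd at 834, 1097 and 1347. Drug efflux and xenobiotic genes had medians of -0.07 and 0.03 (percentiles 13.3 and 71.3), with the efflux pump Abcg2 at 392, 152 and 108.

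Targets of ATF4 and the unfolded protein response had medians of 0.50 and 0.09 (percentiles 99.8 and 95.1), with the glutathione-degrading Chac1 at 441, 659 and 956 and the pseudokinase Trib3 at 84.7, 266 and 374. From empty vector 1 to empty vector 2 the list's median was already 0.367 (percentile 97.19, within the range). Growth arrest genes had medians of 0.57 and -0.02 (percentiles 99.7 and 26.6), with Rbl2 lower at 201.5, 142.5 and 89.2 and Cdkn1b higher at 381, 406 and 552. Hypoxia and glycolysis genes had medians of 0.37 and 0.17 (percentiles 95.2 and 99.96), and 17 of 24 exceeded both arrays, among them the mTOR inhibitor Ddit4 (337, 683 and 978) and the glucose transporter Slc2a1 (3507, 3860.1 and 4925). NF-kB and inflammatory genes had medians of 0.02 and 0.19 (percentiles 7.95 and 99.9), with the serum amyloid Saa3 at 8973, 11517 and 14309 and the chemokine Cxcl1 at 5687, 8128 and 9843. Autophagy and lysosome genes had medians of 0.29 and 0.12 (percentiles 71.5 and 99.1), with the cholesterol carrier Npc2 at 7074, 7653 and 9591. Interferon response genes had medians of -0.25 and 0.10 (percentiles 5.92 and 89.2), with Oasl1 at 30.9, 19.2 and 62.2 and Ifit1 at 109, 47.2 and 25.4. They differed more between the control arrays, with a median of -0.447 from empty vector 1 to empty vector 2 (percentile 0.52, outside the range).

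**Figure D3:**
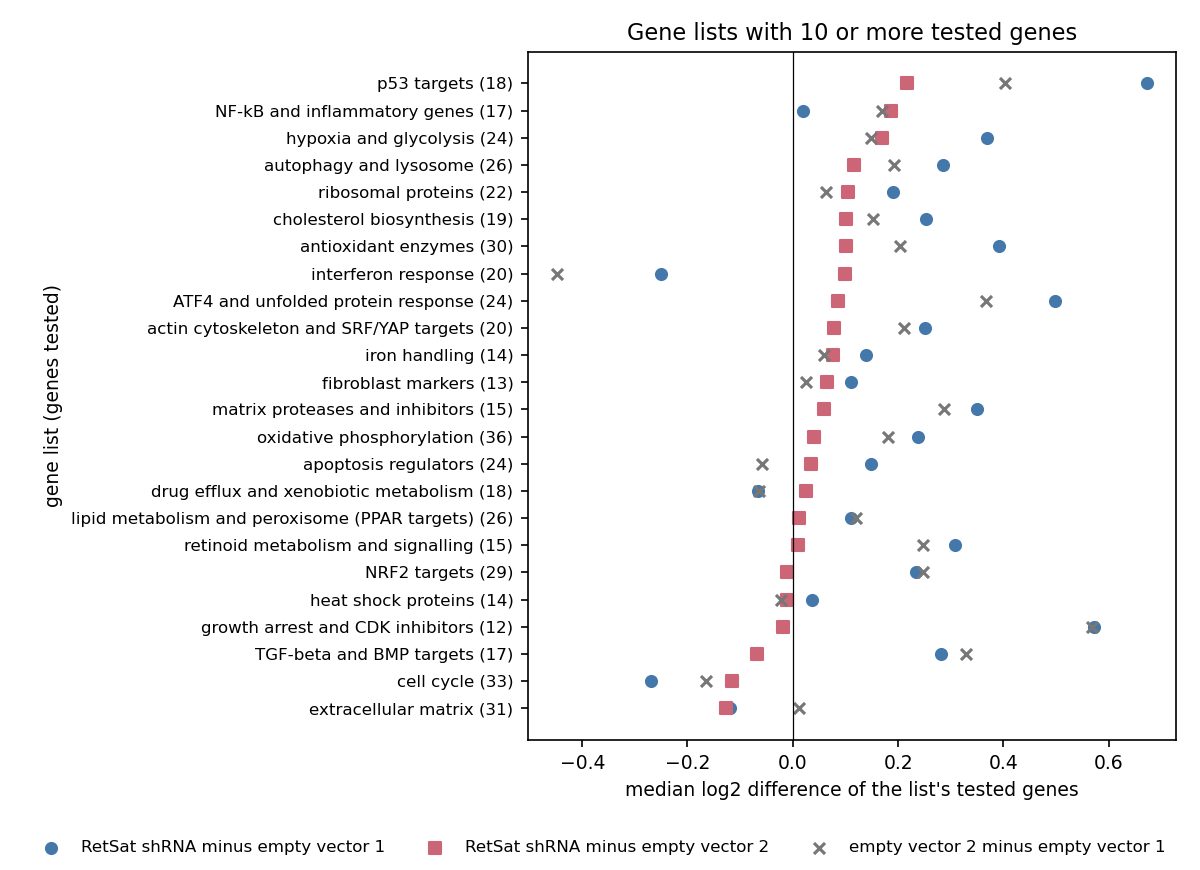
Median log2 difference of each gene list with 10 or more tested genes (x axis), for RetSat shRNA against empty vector 1 (circles), RetSat shRNA against empty vector 2 (squares) and empty vector 2 against empty vector 1 (crosses). Squares lie closest to 0 for most lists, and p53 targets stand at 0.67, 0.22 and 0.40.

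The remaining lists lay within the range of random lists against both arrays or held few tested genes. Medians against empty vector 1 and empty vector 2 were 0.04 and -0.01 for heat shock proteins, 0.15 and 0.03 for apoptosis regulators, 0.35 and 0.06 for matrix proteases and their inhibitors, 0.25 and 0.08 for actin and SRF/YAP targets, 0.28 and -0.07 for TGF-beta and BMP targets, 0.24 and 0.04 for oxidative phosphorylation and 0.19 and 0.11 for ribosomal proteins. The pro-apoptotic Bcl2l11 read 733, 1609 and 1989 and the cathepsin Ctsk read 209.6, 258 and 382. Fibroblast markers had medians of 0.11 and 0.07 over 13 genes and were bright on each array, with Col1a2 at 13012, 13247 and 14057. Markers of other cell types were mostly below the filter, with 3 of 12 muscle, 4 of 12 epithelial, 4 of 12 macrophage and leukocyte and 1 of 10 endothelial genes tested, and medians of -0.28 and 0.24, -0.10 and 0.13, 0.08 and -0.0024, and 0.46 and 1.40. The endothelial value rests on Eng alone, at 49.5, 20.8 and 71.8. Over the 28 lists, 0 genes passed limma over all genes tested, and 1, Retsat, did so adjusted over the list alone.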

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

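The other variance priors and the minimum-change test for Retsat, and the joint omission of empty vector 1 with a stricter filter were chosen after the result was seen. Alternatives left the Retsat difference at -2.20 to -2.71 log2. Leaving out either empty-vector array gave -2.67 to -2.42, with no test. Retsat passed limma under the robust variance prior alone (-2.54, adjusted p = 0.00717), and its adjusted p ran up to 1 elsewhere. The count of genes past limma was 0 except under the robust prior (7 genes, namely Retsat, Prdm11, Fv1, Myo9a, Pou5f2, Crybg3 and Slc22a17, each lower) and with arrays centred on the median (1 gene, Kcnq1ot1), with 32 to 586 genes at an unadjusted p under 0.05 across the alternatives. The count at least 2-fold higher and lower than both empty-vector arrays, 10 and 54, became 0 and 9 at 3-fold, 386 and 414 without a filter, 0 and 1 with the stricter filter, 27 and 92 without an offset, 2 and 9 with the larger offset, and 29 and 182 over every probe set. Quantile normalization gave 25 higher, and 43 lower. Leaving out an empty-vector array gave 78 to 374 higher and 110 to 1104 lower, and leaving out empty vector 1 with the stricter filter gave 4 and 2. The cause was not tested beyond the filters, which keep more or fewer dim genes. Lists outside the range of random lists numbered 7 in the planned comparison, 7 to 8 under the scalings, filters and offsets, and 5 to 9 with an empty-vector array left out, of 28 lists (25 with the stricter filter). They were not the same lists throughout. Retinoid genes came within the range after quantile normalization and with the stricter filter (percentiles 93.3 and 78.1), where heat shock proteins came to lie outside (1.80 and 1.91). Iron handling genes lay outside with the stricter filter (0.6), and growth arrest genes without a filter and with the larger offset (99.69 and 98.13). The other alternatives were not run for the lists. Under the scalings and offsets, 95 of 516 values of the named genes other than Retsat moved by at least 1 SD between the empty-vector arrays, among them 45 of the 93 values of genes past the rule of size. That SD is each gene's own, so small shifts count where the controls were close. Crhr1 counted as moved from 1.06 to 1.09 on centring, and Fv1 as not moved from -2.56 to -1.61 with the larger offset. The count therefore says little about the size of the shifts. With the larger offset Pou5f2 went from -2.54 to -1.46 and Slc22a17 from -2.63 to -1.44. Kcnq1ot1, at -3.26, was -1.47 without empty vector 1 and -5.04 without empty vector 2. No paired analysis was possible because the groups share only the number 2, and a fit without an empty-vector array has no residual degree of freedom. Signal close to the floor limits the dim genes.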

Other observations

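Every test in this part except the length-matched list percentiles was chosen after the result was seen, as were the genes of this paragraph. Brighter genes with the largest difference from both empty-vector arrays, all under 2-fold by at least one of them, included haptoglobin (Hp), an acute-phase protein. It read 1831 and 2527 with the empty vector and 4355 with the shRNA, the cytokine signalling inhibitor Socs3 read 1139, 1688 and 2781, and Rgs16, a regulator of G-protein signalling, read 141, 454 and 794. With the empty-vector arrays close together, the p53-inducible Cdip1 read 262, 269 and 447 (another of its probe sets differed the opposite way), the ubiquitin ligase Siah1a read 379, 374 and 604, the reductase Akr1c12 read 223, 231 and 378, and tissue factor (F3) read 479.8, 470.3 and 727. On the lower side, the mRNA decapping enzyme Dcp2 read 551, 545 and 299, the peroxisome biogenesis factor Pex3 read 479.8, 512 and 278, the kinase Stk16 read 442, 480.4 and 257, and the mitochondrial Letm1 read 371, 371 and 226. None of these genes passed limma (adjusted p = 1 for each).

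The 6 protein-coding genes nearest to Retsat in the annotation order showed no common reduction. Their log2 differences from empty vector 2 were 0.14 for Capg, 0.56 for Elmod3, 0.09 for Kcmf1, 0.14 for Sh2d6, 0.45 for Tcf7l1 and -0.13 for Tgoln1. From empty vector 1 they were 0.65, 0.87, 0.68, 1.11, -0.01 and -0.30 in the same order, so Tgoln1 was lower than both. Over 5131 genes with a second tested probe set, the difference between RetSat shRNA and empty vector 2 correlated at r = 0.118 between the 2 probe sets of a gene, against 0.626 for RetSat shRNA and empty vector 1 and 0.599 for the empty-vector arrays. A difference from empty vector 2 on 1 probe set thus mostly said little about the other, which limits single genes read from 1 probe set. These correlations are across genes.

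Empty vector 1 stood apart from the other arrays. Scaling is argued against, since 1542 genes differed at least 2-fold between the empty-vector arrays after quantile normalization (1381 before, 1252 of them in both counts), compared with 221 between RetSat shRNA and empty vector 2. A swap of its label with the RetSat shRNA array is argued against by Retsat itself, which differed by 0.248 log2 between the empty-vector arrays. The difference of empty vector 2 from empty vector 1 fell with the length of the gene in the genome (Spearman rho -0.254 over 10827 genes). Longer genes thus tended to read higher on empty vector 1. The rho was -0.305 for RetSat shRNA minus empty vector 1 and -0.136 for RetSat shRNA minus empty vector 2. A trend with gene length is not the whole cause, since 1452 genes were at least 2-fold apart once it was removed, 1063 of them among the 1381 before. This array is the only one numbered 1, and a batch or day shared by the arrays numbered 2 stays open, as do labelling chemistry, growth state and a label exchanged with a sample outside the series; what the number stands for is not given in the sources used here, and no biological explanation was tested.

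The 64 genes at least 2-fold from both empty-vector arrays may be mostly noise between arrays, since 66 genes met the same rule with empty vector 2 as the lone array. That account does not extend to Retsat, which was lower on both of its probe sets. An effect of the shRNA on single dim genes stays open.

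Higher p53 targets with lower cell cycle genes on RetSat shRNA form a hypothesis of slower growth, not a finding. The lower extracellular matrix genes were not tied to growth by any test. Of the 33 cell cycle genes, 16 lay below both empty-vector arrays, 2 above both and 15 neither. Mki67 (125 on empty vector 2 and 122 on RetSat shRNA), Top2a (655 and 624) and Cdk1 (4165 and 4210) were nearly level, whereas Mcm4 was lower (1811 and 1338). The growth arrest and CDK inhibitor list lay within the range of random lists against empty vector 2 (median -0.018, percentile 26.6). Its 0.573 against empty vector 1 was matched by 0.569 between the empty-vector arrays. As fixed, that list also holds Ccnd1, Ccnd2 and Ccnd3, which are cyclins and not inhibitors, so its median cannot decide for or against the hypothesis. A trend with gene length is argued against for the differences of the p53, cell cycle and matrix lists from empty vector 2. Their medians stayed at percentiles of 99.99, 0.02 and 0.06 among random lists matched on gene length and expression. Against empty vector 1 the percentiles were 100, 0.01 and 1.705. Between the empty-vector arrays the matrix list came within the range (12.71, from 1.43 without length matching). There cell cycle genes stayed outside it (0.11) and p53 targets within it (96.25). Spread between arrays of one group could account for the first 2 lists, whose medians differed by 0.404 and -0.165 between the empty-vector arrays. For the matrix list that spread was 0.0121 as deposited and -0.124 relative to the median of all genes, so it cannot be told apart from spread between arrays, because the answer depends on the centring. An effect of the shRNA and selection of the resistant cells both stay open and were not tested.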
